A study of Arabidopsis thaliana with 12 samples.

How the data were processed

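The signal intensity of each probe set was computed by the authors with MAS5, per the submitters' processing notes, before the values were deposited, and it was on a linear scale; the MAS5 version was not given in the sources used here. The trimmed mean signal was 500.05 to 500.06 on all 12 arrays, so the deposited values had been scaled to a common target and no further scaling was applied in the main fit. Detection calls were not used here. The 12 value columns were matched to the samples by their identifiers, and 0 columns belonged to no sample.

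Probe sets took their gene from the platform table, checked against the RefSeq table of the TAIR10.1 assembly. After 64 control probe sets were left out, 13513 had 1 gene (13436 of them found in the RefSeq table, at 13286 loci), 503 had several and 8730 were left unnamed; genes are named in the text only for probe sets with 1 gene. Those named were set by a rule: for the genotype comparisons and Pst in wild type the 10 largest rises and 10 largest falls among called genes whose groups did not overlap, for Pst in lht1 5 and 5, for the difference the 10 largest, and up to 4 members of each list. Alternatives were run for the genes under this rule. Of the 14 genes that were always to be named, only PDF1.2 had a named probe set, and LHT1 was not analysed here. Of 352 list members 40 were named and 39 measured, and the lists of amino acid transporters, nitrogen assimilation and amino acid metabolism, and cell division had 0 measured members.

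Signals below 8.1, the 10th percentile, were raised to that floor, and a probe set was tested when at least 3 of 12 arrays exceeded 103.7, the 40th percentile. This left 15178 probe sets, 8279 with 1 gene, 303 with several and 6596 unnamed. Log2 signals were fitted with limma on the 4 groups, with an intensity trend in the variance (prior degrees of freedom 7.376, residual 8), and p values were adjusted by the Benjamini-Hochberg method within each comparison, with 0.05 as the threshold. The 5 comparisons were lht1 against wild type untreated and after Pst, Pst against untreated in wild type and in lht1, and the difference of the Pst response. Fold values are ratios from the log2 change. Where all 3 arrays of the lower group lay under 103.7, the fold is given as a lower bound, the other group's geometric mean over that value, and no fold is given where the bound is under 1.

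The 20 gene lists, the comparisons, the threshold, the floor, the filter and the alternatives were chosen before the data were examined. Lists with at least 3 measured members were tested with camera at a preset correlation of 0.01, with an estimated correlation and fry as alternatives; fry tests movement on balance and does not compare a list with other genes. A further 22 families were added after the names were seen and before any test. Alternatives were quantile normalization, equal medians, a floor at the 25th percentile, a pseudocount of 34.3 in place of the floor, no filter, a filter at the 60th percentile, no trend, array weights, only the arrays compared, replicate and array-series blocks, only the bot07 arrays, a 2-fold threshold, and each array left out in turn.

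Recovery was tested on simulated data with 200 of 15178 probe sets changed. At log2 sizes of 1, 2 and 3, 33%, 80% and 88% were recovered for the untreated genotype comparison, 42%, 84% and 98% after Pst, 46%, 76% and 92% for Pst in wild type, 48%, 84% and 90% for Pst in lht1 and 16%, 70% and 82% for the difference, with 2.92% to 7.53% of calls false. The expected correlation and covariance of log2 changes came from 100 simulated data sets, with noise drawn separately for each probe set. Fewer such data sets gave the simulated shared calls and the simulated covariance for splits of the untreated wild-type arrays. R 4.3.3, limma 3.58.1, Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9 were used.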

Results

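Transcript levels were measured in fully expanded leaves of 3-week-old Arabidopsis thaliana plants of the Columbia-0 ecotype, grown with 8 h of light per day at 20 °C. The plants were wild type or carried a knockout of LHT1, lysine histidine transporter 1, which takes amino acids up across the plasma membrane. Leaves were either left untreated or infiltrated with Pst (Pseudomonas syringae pv. tomato, a bacterial leaf pathogen) and taken 48 h later. Each of the 4 groups held 3 biological replicates, each made from several leaves mixed together and hybridised to its own 1-colour Affymetrix array, which gives 12 arrays. The labels describe no leaves infiltrated without bacteria, so each comparison of Pst with untreated leaves also holds the effect of infiltration. LHT1 itself was not analysed here, so the genotype labels were taken as given.

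Of the probe sets on the arrays 15178 were bright enough to be tested, 8279 of them with a single named gene, and the median signal per array was 168 to 196. Pairs of arrays within a group correlated at r = 0.877 to 0.958 on the log2 scale across probe sets, which are not independent replicates. Wild-type and lht1 arrays correlated at a median r of 0.832, whereas untreated and Pst arrays correlated at 0.902 within wild type and 0.925 within lht1. The first principal component, with 38.5% of the variance, separated all 6 lht1 arrays from all 6 wild-type arrays. Wild-type Pst replicate 3 lay apart from the rest on the second component, at -81.6, and lht1 untreated replicate 3 lay apart on the third component, at 69.2. The array codes in the labels fell into a bot07 series (replicates 1 and 2, 8 arrays) and a bot08 series (replicate 3, 4 arrays), so every group was split alike between them. The 25S ribosomal RNA control averaged 4670 ± 1416 (SD, n = 8) in bot07 and 11565 ± 3354 (SD, n = 4) in bot08, and the BioC spike averaged 1035 ± 222 and 3246 ± 541. The 3-prime to 5-prime signal ratio of the GAPDH control is a measure of RNA integrity, and a higher ratio stands for more degraded RNA. It was 2.346 ± 0.397 (SD, n = 3) in untreated wild type, 2.170 ± 0.154 in untreated lht1, 2.297 ± 0.268 in wild type after Pst and 1.714 ± 0.357 in lht1 after Pst. In that last group it was 1.746, 2.054 and 1.344 on replicates 1, 2 and 3.

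**Figure D1:**
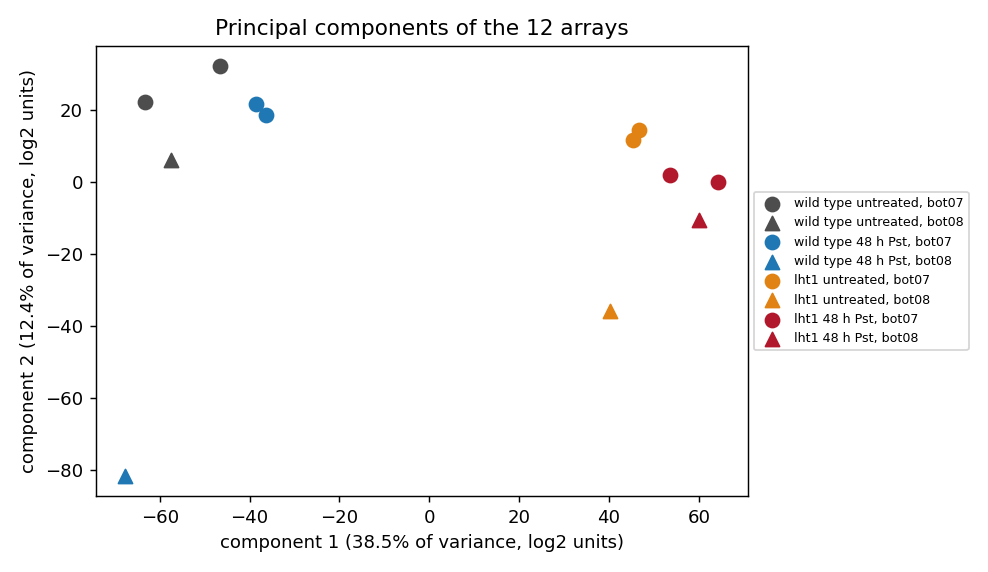
Principal components of the 12 arrays from the log2 signals of the tested probe sets, with component 1 (38.5% of the variance) on the x axis and component 2 (12.4%) on the y axis, in log2 units. Each point is an array, with colour for the group and shape for the array series; the 6 lht1 arrays lie at 40.2 to 64.3 on component 1 and the 6 wild-type arrays at -67.7 to -36.3.

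The series was designed to profile how loss of LHT1 changes gene expression in leaves, and the genotypes were compared first without infection. Among the named genes with the largest changes, UGT76B1, a glucosyltransferase that acts on salicylic acid and isoleucic acid, averaged 13.4 ± 5.91 signal units in wild type and 740 ± 373 in lht1 (SD, n = 3 each), which was at least 6.60-fold higher (log2 change 5.71, SE 0.42, adjusted p = 2.19e-07). AT3G13610, the hydroxylase of scopoletin synthesis, rose at least 6.17-fold, from 22.7 ± 26.5 to 651 ± 141 (log2 change 5.40, SE 0.73, and 6.30 without wild-type untreated replicate 2). AT4G12490, a lipid-transfer-like protein, rose 34.5-fold from 412 ± 49.7 to 14530 ± 4395 (log2 change 5.11, SE 0.21, adjusted p = 2.9e-10). In the other direction AT3G62550, a universal stress protein-like gene, decreased from 9307 ± 366 to 300 ± 81.2 (log2 change -4.99, SE 0.23, adjusted p = 1.18e-09).

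The other genes among the 10 largest rises in untreated lht1 included AT3G28510 and AT1G43910, both AAA-type ATPases, at log2 changes of 5.97 and 5.41. AT1G57630, a TIR-domain protein, AT1G68620, a carboxylesterase, and AT2G42360, a RING-finger protein, rose by 5.09, 5.07 and 4.84 on the log2 scale, and AT3G18250 and AT5G46230 by 5.17 and 4.84. Among these, AT3G28510, AT1G43910, AT1G57630, AT5G46230 and AT2G42360 were dim on all 3 untreated wild-type arrays, and their bounds ran from at least 4.13-fold for AT2G42360 to at least 6.84-fold for AT1G43910. With a pseudocount in place of the floor these 5 had log2 changes of 3.22 for AT2G42360 to 3.78 for AT3G28510. Without wild-type untreated replicate 2 AT1G43910 stood at 6.39 and AT3G18250 at 5.80, and AT1G68620 stood at 5.73 without replicate 1 and 4.18 without replicate 3. AT3G18250 and AT1G68620 averaged 66.4 ± 54.3 and 79.6 ± 63.3 in untreated wild type, under the brightness level for testing, so their rises have no exact size. The 10 largest falls also held AT1G20030, a thaumatin-like protein, at -4.20, AT1G11210 at -3.79 and IAA29, a member of the auxin-response repressor family, at -3.77, all 3 to averages under that level in untreated lht1 (51.2 ± 66.2, 69.6 ± 63.2 and 70.5 ± 57.8). AT4G01130, a GDSL-type lipase, was dim on all 3 untreated lht1 arrays and at least 4.99-fold lower. Single arrays of untreated lht1 moved these values: without replicate 1 AT1G20030 stood at -5.33 and AT1G11210 at -3.21, without replicate 2 IAA29 at -2.54, and without replicate 3 AT1G20030 at -3.38, AT1G11210 at -4.51 and IAA29 at -4.41. The fitted change of AT4G01130 went from -3.78 to -4.37 without replicate 1. AT5G61590, an AP2/ERF transcription factor, fell 11.1-fold from 2348 ± 323 to 212 ± 37.7 (n = 3 each). Fes1B, AT4G32340 and ORA47, an AP2/ERF factor of the jasmonate response, changed by -3.41, -3.35 and -3.24. The ORA47 value was set by lht1 untreated replicate 3, at 2359 signal units against 130 on each of the other arrays of that group: it was -4.63 without replicate 3 and -2.54 without replicate 1 or 2. AT5G45310 was dim on all 3 untreated lht1 arrays and at least 1.73-fold lower (fitted log2 change -3.42, adjusted p = 0.0126), a call that ended without wild-type untreated replicate 1 (-3.35, adjusted p = 0.0627) or replicate 2 (-3.15, adjusted p = 0.0699); its adjusted p ran from 0.00136 to 0.0699 over 24 alternatives.

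Of the 20 gene lists fixed in advance, 5 had at least 3 named and measured members and were tested. The measured members of both stress-hormone lists among these shifted in untreated lht1. These were only 3 of 18 for the salicylic acid response and 3 of 15 for abscisic acid and dehydration. Whole hormone responses were therefore not tested. In the salicylic acid response list UGT76B1 and GRX480, a glutaredoxin, rose, the latter 3.17-fold (log2 change 1.67, SE 0.21), while WRKY53, a transcription factor of defence and senescence, stood at 1.01 (SE 0.40, adjusted p = 0.0976) and did not pass. The WRKY53 value rested on lht1 untreated replicate 3, at 729 signal units against 210 and 195 on the other arrays of that group: it was 0.39 without that array and 1.34 without replicate 2, where it passed. The list's median log2 change was 1.67 over 3 members (camera, adjusted p = 0.000284), and 3 members, WRKY53 among them, passed when adjusted over the list alone. All 3 measured members of the abscisic acid and dehydration list fell: COR15B by 2.26, COR47 by 1.86 and COR15A by 1.43 on the log2 scale, all of them cold- and dehydration-induced protective proteins (adjusted p = 3.02e-05, 3 adjusted over the list alone). With an estimated correlation these lists stood at adjusted p = 0.0371 and adjusted p = 0.0120, the highest over their alternatives. The lowest from camera were 3.52e-05 and 7.85e-07, and fry, which does not compare a list with other genes, gave 1.24e-05 and 1.41e-06. Within the bot07 arrays the medians were 1.65 and -2.16, within the bot08 pair 2.39 and -1.35, and with the array series as a block the adjusted p was 0.000619 and 3.37e-05.

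The redox, photosynthesis and reference lists did not shift as groups in untreated leaves (camera, adjusted p = 0.376, 0.365 and 0.854). Among 4 redox genes GR1, a glutathione reductase, rose 2.82-fold (SE 0.16 on the log2 scale), and 2 passed when adjusted over the list alone. TAPX (-0.43) did not pass but did so without wild-type untreated replicate 3 (-0.56) and in 4 other alternatives, and SAPX (0.44) without lht1 untreated replicate 3 (0.69) and in 2 others. Among 9 photosynthesis genes LHCB4.3, a minor antenna protein, rose by 1.31, while LHCB4.2 decreased by 0.69 on the log2 scale (SE 0.15, adjusted p = 0.00403), with 3 passing when adjusted over the list alone. PSAN, a subunit of photosystem I, stood at -0.46 (adjusted p = 0.0369), a call that ended when any of the 6 untreated arrays was left out (-0.43 to -0.49) and in 4 other alternatives, with -0.27 after quantile normalization (adjusted p = 0.121, over a range of 0.00536 to 0.121). None of the 3 reference transcripts passed, with AT4G34270 at -0.34, GAPC2 at 0.12 and AT2G28390 at -0.05.

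Lists with 1 or 2 measured members were described gene by gene and not tested. AT5G52810, an enzyme of pipecolate synthesis, rose 7.54-fold in untreated lht1, from 299 ± 35.3 to 2243 ± 41.7, and PDF1.2, a defensin, rose 3.32-fold from 234 ± 79.8 to 794 ± 353. BSMT1, the methyltransferase that forms methyl salicylate, rose by 3.19 on the log2 scale (adjusted p = 0.0150), though not without wild-type untreated replicate 2 (3.01), lht1 untreated replicate 1 (2.79) or lht1 untreated replicate 2 (2.73), nor with no intensity trend (adjusted p = 0.0584, over a range of 0.000357 to 0.0717), and it stood at 4.04 without lht1 untreated replicate 3. Its untreated wild-type signals were 92.8, 75.2 and 128.4, with an average under the brightness level, so this rise has no exact size. AT2G04400, indole-3-glycerol phosphate synthase of tryptophan synthesis, rose 2.43-fold. Of the 2 endoplasmic reticulum chaperones, CRT1b, a calreticulin, rose 1.78-fold and the co-chaperone ATERDJ3B stood at 2.05-fold (log2 change 1.04, adjusted p = 0.0130), which did not pass without wild-type untreated replicate 2 (0.93), lht1 untreated replicate 1 (0.82) or lht1 untreated replicate 2 (0.80), with no intensity trend (adjusted p = 0.0591) or with only the untreated arrays fitted (adjusted p = 0.0577, over a range of 3.14e-06 to 0.0698). GI, a clock gene, decreased by 0.84 on the log2 scale (SE 0.16). SAG101, EFR, BIK1, THI2.1, GSTU20, BCAT4, AT2G31790, SAG29, WRKY6 and FMA, from the lists of salicylic acid synthesis, immune receptors, jasmonate, glutathione transferases, aliphatic glucosinolates, senescence and other tissues, did not pass, with log2 changes from -0.46 for BCAT4 to 1.43 for SAG101 and, from a dim level, 2.299 for EFR. SAG101 passed without wild-type untreated replicate 2 (2.15) and AT2G31790 without lht1 untreated replicate 3 (0.66). The SAG101 value rested largely on wild-type untreated replicate 1, at 14.1 signal units against 172.9 and 106.4 on the other arrays of that group.

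In total, 2788 of 15178 tested probe sets differed between untreated lht1 and wild type (limma, adjusted p under 0.05), 1456 higher and 1332 lower in lht1, and 1378 of them by at least 2-fold. The 3 arrays of the genotypes did not overlap for 5404 probe sets, 35.6% against 10% by chance. With the array series as a block 3385 differed, and within the bot07 arrays alone 3343. Of these bot07 calls 87.38% went the same way in the bot08 pair, against 67.64% of all tested probe sets.

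**Figure D2:**
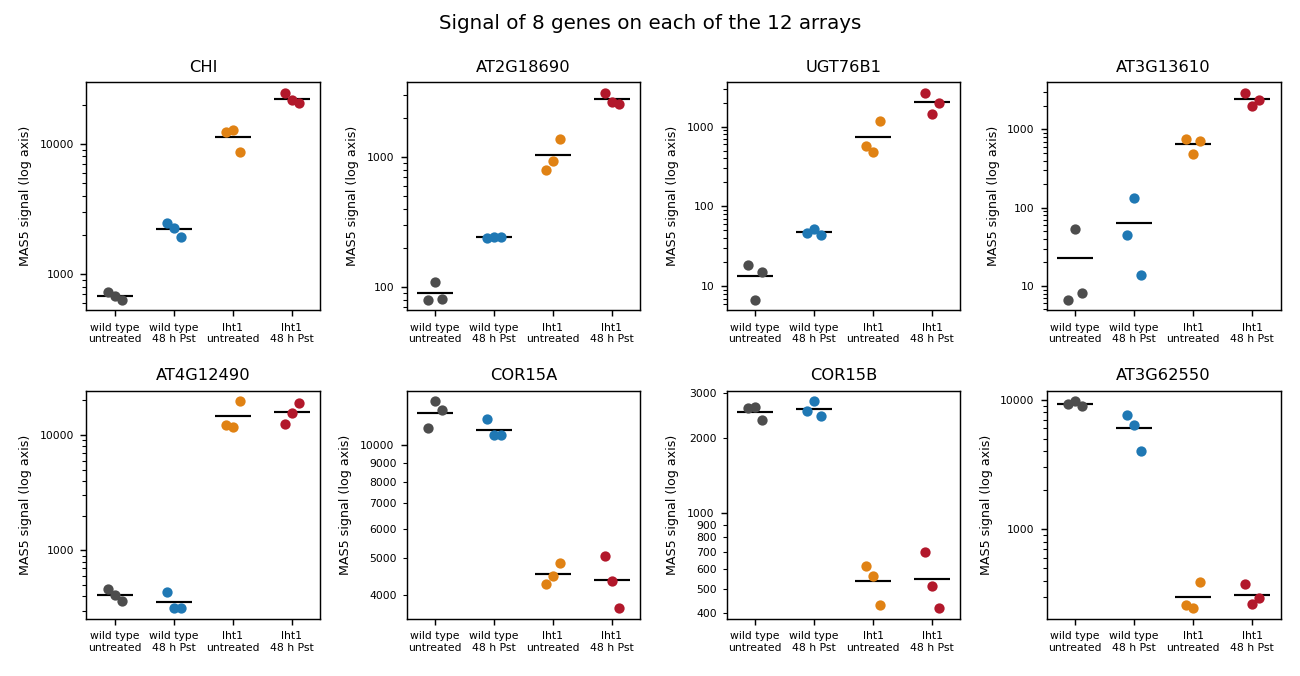
MAS5 signal (log axis) of 8 genes on each of the 12 arrays, with a point per array and a bar at the mean of the 3 arrays of each group. CHI averaged 684 in untreated wild type, 2215 in wild type after Pst, 11210 in untreated lht1 and 22250 in lht1 after Pst, while COR15A, COR15B and AT3G62550 were lower on all 6 lht1 arrays than on all 6 wild-type arrays.

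The genotypes were next compared 48 h after Pst. AT4G12490 rose 44.2-fold (log2 change 5.47). JRG21, a jasmonate-regulated oxygenase, was higher in lht1, at 5244 ± 2330 against 102 ± 73.0 signal units (SD, n = 3 each, log2 change 6.06, SE 0.61, adjusted p = 4.47e-06). AT3G18250 averaged 4236 ± 187 in lht1 against 93.6 ± 64.1 in wild type, and AT3G13610 2432 ± 492 against 64.5 ± 62.4, with fitted log2 changes of 5.86 and 5.77. The wild-type averages of these 3 genes lay under the brightness level for testing, as did 1 of the single wild-type arrays for JRG21 and AT3G18250 and 2 for AT3G13610, so their rises have no exact size. Without wild-type Pst replicate 3 JRG21 stood at 5.06, AT3G18250 at 5.07 and AT3G13610 at 4.95, and AT3G13610 at 6.58 without replicate 2. UGT76B1 reached 2027 ± 621 in lht1 against 47.3 ± 4.55 in wild type, at least 18.9-fold higher. AT1G11210 averaged 649 ± 109 in wild type and 9.73 ± 7.64 in lht1 after Pst, at least 6.20-fold lower (log2 change -5.92, SE 0.57, adjusted p = 2.78e-06).

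Further rises after Pst were found for UGT73D1, a glycosyltransferase (5.75), AT1G26420, a berberine bridge enzyme-like protein (5.50), AT1G68620 (5.48), AT1G43910 (5.22) and AT2G38240, an oxygenase (5.13), given as log2 changes. UGT73D1, AT1G26420, AT1G68620 and AT1G43910 were dim on all 3 wild-type Pst arrays, with bounds of at least 5.34, 3.67, 34.2 and 6.74-fold. AT2G38240 averaged 88.1 ± 72.8 in wild type, with 2 arrays under the brightness level, and stood at 4.12 without wild-type Pst replicate 1, 5.84 without replicate 2 and 5.82 without lht1 Pst replicate 1. Falls were found for AT3G62550 at -4.24, ORA47 at -3.98, AT4G29780 at -3.58, IAA29 at -3.53 and CML38, a calmodulin-like protein, at -3.36. AT4G29780, IAA29 and CML38 averaged under the brightness level in lht1 after Pst, so their falls have no exact size. IAA29 stood at -2.50 without lht1 Pst replicate 1 and -4.18 without replicate 2, and CML38 at -2.35 without replicate 3. AT5G66650, AT3G46370, a receptor-like kinase, AT1G20030 and AT5G45310 were dim on all 3 lht1 Pst arrays and were at least 2.70, 3.04, 4.38 and 1.39-fold lower. ORA47, CML38 and AT4G29780 had wide spreads in untreated lht1 (873 ± 1287, 287 ± 311 and 756 ± 1136) and narrow ones after Pst (198 ± 54.4, 81.7 ± 59.4 and 93.9 ± 19.6).

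All 3 measured members of the salicylic acid response list rose in lht1 after Pst, WRKY53 4.07-fold, GRX480 3.96-fold and UGT76B1 as above (median log2 change 2.02, camera adjusted p = 6.27e-05, 3 adjusted over the list alone). COR15B, COR47 and COR15A were again lower, at log2 changes of -2.28, -2.14 and -1.35 (median -2.14, adjusted p = 3.23e-05, 3 adjusted over the list alone). Both lists also shifted with an estimated correlation, at adjusted p = 0.0242 and adjusted p = 0.0123, the highest over their alternatives. The lowest from camera were 5.38e-06 and 2.61e-06, and fry, which makes no comparison with other genes, gave 4.09e-06 and 1.3e-06. The medians were 2.27 and -2.12 within bot07 and 1.70 and -2.18 within the bot08 pair, with adjusted p = 0.000168 and 3.83e-05 with the array series as a block.

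Photosynthesis genes averaged lower in lht1 after Pst, with 5 of 9 called (5 adjusted over the list alone) and a median log2 change of -0.51 (camera, adjusted p = 0.00294). The list's call was lost at adjusted p = 0.127 with an estimated correlation and after quantile normalization, where the median was -0.17 (adjusted p = 0.386, over a range of 0.000883 to 0.386). PRK, the phosphoribulokinase of the Calvin cycle, decreased by 0.68 on the log2 scale (SE 0.14) and passed in all 24 alternatives. LHCB4.2 and PSAN stood at -0.76 and -0.67 (SE 0.15 and 0.14) and lost their calls after quantile normalization, at -0.28 each (adjusted p = 0.108 and 0.107, the highest over their alternatives, with the lowest at 0.00055 and 0.00133). LHCB4.1 stood at -0.70 (SE 0.20, adjusted p = 0.0236), a call that ended without wild-type Pst replicate 3 (-0.48), lht1 Pst replicate 1 (-0.64) or lht1 Pst replicate 2 (-0.64), with no filter on dim probe sets (adjusted p = 0.0953) or with no intensity trend (adjusted p = 0.061), and that shrank to -0.17 after quantile normalization (adjusted p = 0.378, over a range of 0.00108 to 0.378). Within bot07 the median was -0.49, within the bot08 pair -0.61, and with the series as a block the adjusted p was 0.000883. The GAPDH ratio was lowest in the same group of arrays, at 1.714 ± 0.357.

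The redox list did not shift (adjusted p = 0.533, 4 adjusted over the list alone), because its members parted: GR1 and SAPX, a chloroplast ascorbate peroxidase, rose by 1.38 and 1.01, while TAPX, the thylakoid ascorbate peroxidase, fell by 0.66 on the log2 scale. GR, a plastid glutathione reductase, stood at -0.43 (adjusted p = 0.0314), which did not pass without wild-type Pst replicate 2 (-0.47) or 3 (-0.36) or without lht1 Pst replicate 2 (-0.35) or 3 (-0.42), within bot07 (-0.35, adjusted p = 0.0772) or with no intensity trend (adjusted p = 0.0818, over a range of 0.0127 to 0.136). The reference list did not shift with camera (adjusted p = 0.434), and no member passed in limma. Its median log2 change was -0.32 all the same, with 2 of 3 members lower. The median was -0.20 within bot07 and -0.51 within the bot08 pair. With fry, which makes no comparison with other genes, the list had adjusted p = 0.0317. Among the untested lists AT5G52810 rose 5.16-fold, BSMT1 at least 4.94-fold (log2 change 4.35, but 3.53 without wild-type Pst replicate 2 and 5.37 without lht1 Pst replicate 1), PDF1.2 2.93-fold, AT2G04400 2.92-fold, ATERDJ3B 2.54-fold and CRT1b 1.90-fold. BIK1, a receptor-associated immune kinase, stood at 1.76-fold (log2 change 0.82, adjusted p = 0.0169), but not past the threshold without wild-type Pst replicate 1 (0.76) or 2 (0.72) or lht1 Pst replicate 1 (0.72). GI stood at -0.61 (adjusted p = 0.0121) and at -0.49 without lht1 Pst replicate 1, where it did not pass. SAG101, EFR, THI2.1, GSTU20, BCAT4, AT2G31790, SAG29, WRKY6 and FMA did not pass, at -0.19 for FMA to 2.69 for WRKY6. THI2.1 passed without wild-type Pst replicate 1 (1.66), SAG29 without lht1 Pst replicate 1 (2.87) and SAG101 without wild-type untreated replicate 1 (1.32).

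After Pst 3141 probe sets differed between the genotypes, 1549 higher and 1592 lower in lht1, and 1577 of them by at least 2-fold. The arrays of the genotypes did not overlap for 5688 probe sets, 37.5% against 10% by chance. With the series as a block 3685 differed, and within bot07 3351. Of these bot07 calls 94.96% went the same way in the bot08 pair, against 70.6% of all tested probe sets.

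The untreated and Pst comparisons of the genotypes share no array. Of their calls 1916 were the same in direction, 969 higher and 947 lower in lht1, and 2 were opposite, where independent lists would share 288. Log2 changes correlated at r = 0.722 (Spearman rho 0.649) across probe sets, with a covariance of 0.591 against -0.000164 in simulated unchanged groups. AT4G12490, UGT76B1, COR15A, COR15B and AT3G62550 were called in the same direction in both comparisons.

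**Figure D3:**
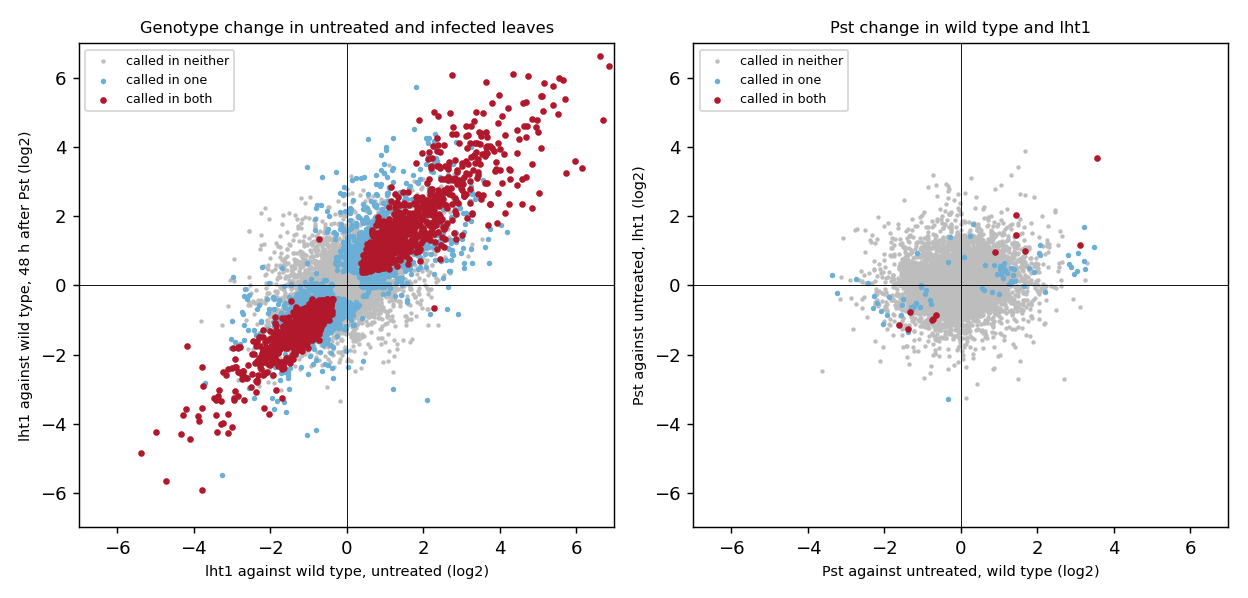
Log2 changes of the 15178 tested probe sets, each a point, coloured by whether it was called in neither, in a single one or in both of the comparisons on the axes. In the left panel (lht1 against wild type, untreated on x and after Pst on y) the changes run along the diagonal at r = 0.722, and in the right panel (Pst against untreated, wild type on x and lht1 on y) they correlate at r = 0.105.

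The response of wild-type leaves to Pst at 48 h was smaller than the difference between the genotypes. CHI, a chitinase, rose 3.23-fold, from 684 ± 43.6 to 2215 ± 269 signal units (SD, n = 3 each, log2 change 1.69, SE 0.15, adjusted p = 4.28e-05). AT4G17470, a thioesterase, fell 4.26-fold from 2730 ± 376 to 640 ± 83.0 (log2 change -2.09, SE 0.27, adjusted p = 0.00116). Alternatives were run for 19 of the 24 called genes with a single name, and of these 19 only CHI and AT4G17470 passed in all 24 alternatives.

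AT1G10340, an ankyrin-repeat protein, and AT2G18690, a membrane protein, rose from untreated averages of 101.4 ± 29.3 and 90.2 ± 16.3, under the brightness level, to 375 ± 62.2 and 241 ± 1.07 (log2 changes 1.92 and 1.43), with the call lost when only the 6 wild-type arrays were fitted (adjusted p = 0.0596 and 0.325, the highest over their alternatives, with the lowest at 0.000163 and 0.00065). AT3G28220 decreased 2.46-fold (adjusted p = 0.00358) and did not pass with no intensity trend (adjusted p = 0.0619, over a range of 6.28e-05 to 0.0619). AT2G44240 and AT5G59670, a receptor-like kinase, were dim in untreated wild type and rose at least 3.75-fold and 3.16-fold. Their calls were lost with no intensity trend (adjusted p = 0.0517 each) and with only the wild-type arrays fitted (adjusted p = 0.051 and 0.0596), with the lowest over the alternatives at 3.82e-05 and 0.000509. The fitted log2 change of AT2G44240 was 3.57, and 2.85 and 4.31 without wild-type untreated replicates 2 and 3. AT3G28510 stood at 3.47 on the log2 scale from a dim level, with no bound above 1, but at 1.39 with the floor at the 25th percentile (adjusted p = 0.264), and its call was also lost with only the wild-type arrays fitted (adjusted p = 0.548, the highest over its alternatives, with the lowest at 0.000302). AT2G32160, a methyltransferase, stood at 1.32 and did not pass without wild-type untreated replicate 3 (1.17) or with no intensity trend (adjusted p = 0.083, over a range of 0.000266 to 0.083).

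Of the other genes run through the alternatives, those lost in 3 to 17 of 24 were AT1G13470 (log2 change 2.08, and 1.45 without wild-type untreated replicate 1) and ZCF37 (2.03), both dim in untreated leaves (at least 1.76-fold and 1.52-fold), AT1G13750 (1.38) and AT5G52810 (1.03) above untreated leaves, and AT1G52000, a jacalin-type lectin (-1.39), AT2G37870 (-1.14), AT2G34810 (-1.03), AT5G19120 (-0.93), AT1G66100, a thionin (-0.73), and AT1G62660, a vacuolar invertase (-0.65), below them. AT3G48080, AT3G28540, AT5G55450, AT1G66880 and AT3G04210 were also called, at log2 changes of 0.87 to 1.31, and are named here after their values were seen, without alternatives. Of the 19 calls that were run, 8 were lost without wild-type untreated replicate 1, 6 without replicate 2 and 8 without replicate 3, and 8, 7 and 6 without wild-type Pst replicates 1, 2 and 3. Without lht1 untreated replicates 1 or 2, which enter through the shared spread, 5 were lost each, without replicate 3 none (0), and without any single lht1 Pst array 4.

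None of the 5 tested lists shifted in wild type after Pst (camera, adjusted p = 0.178 for the salicylic acid response and 0.734 for the abscisic acid, redox, photosynthesis and reference lists), against 0 with an estimated correlation and 0 with fry. Adjusted over the list alone, 1 salicylic acid response gene passed and 0 of the other 4 lists. UGT76B1 was dim on all 6 wild-type arrays, so neither its log2 change of 1.85 (adjusted p = 0.0741) nor its pass without lht1 untreated replicate 3 (1.85) was read as a rise. WRKY53 stood at 0.31 and GRX480 at -0.02 on the log2 scale. COR15A, COR15B and COR47 stood at -0.15, 0.03 and -0.17, and GR1 at 0.16. In the untested lists AT5G52810 alone passed over all probe sets. PDF1.2 (1.27) was the 1 measured member of its list, so its p under 0.05 there was unadjusted. BSMT1 (-1.94) and THI2.1 (-1.87) passed when adjusted over the 2 measured members of their list. BSMT1 and THI2.1 were dim on all 3 wild-type Pst arrays. The log2 changes of BCAT4 and SAG101 were -0.55 and 0.83.

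In wild type 83 probe sets changed after Pst, 48 higher and 35 lower, 24 of them with a single named gene, and 68 changed by at least 2-fold. The groups did not overlap for 1978 probe sets, 13.0% against 10% by chance, and 1170 had an unadjusted p under 0.05 where 759 were expected by chance. With the series as a block 108 changed, and within bot07 121. Of these bot07 calls 90.08% went the same way in the bot08 pair, against 52.64% of all tested probe sets. The count was 49 without wild-type untreated replicate 1, 49 without replicate 3 and 55 without wild-type Pst replicate 2, 55 with no filter on dim probe sets, 27 with no intensity trend and 149 with array weights.

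The genes that Pst changed in wild type were then set beside the genotype difference in untreated leaves. Of the 48 probe sets higher after Pst in wild type, all 48 averaged higher in untreated lht1 than in untreated wild type, 45 of them were called higher there, and 41 lay above the level of wild type after Pst. CHI averaged 11210 ± 2235 in untreated lht1 against 2215 ± 269 in infected wild type, and AT2G18690 1031 ± 304 against 241 ± 1.07. Of the 35 lower after Pst, 7 were called lower in untreated lht1, 10 were called higher and 18 were not called; AT1G66100 averaged 9672 ± 999 in untreated wild type, 5824 ± 311 in infected wild type and 18670 ± 576 in untreated lht1. In all, 52 of the 83 calls went the same way in both comparisons and 10 the opposite way, where independent lists would share 7.68. Both comparisons use the untreated wild-type arrays: simulated unchanged groups against those arrays gave 0 shared calls, r = 0.4999 and a covariance of 0.107, beside the observed r = 0.388 and covariance of 0.185 (difference 0.0780). With no change in any simulated group almost nothing is called. The 0 shared calls were therefore fixed in advance and cannot show what the shared arrays add to the 52. Part of the excess may come from the shared untreated wild-type arrays, and the shared count was 33 without wild-type Pst replicate 1, 33 with no filter on dim probe sets and 32 with only the arrays of the groups compared.

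In lht1, SBT3.5, a subtilisin-like protease, rose 2.71-fold after Pst, from 955 ± 123 to 2583 ± 248 signal units (SD, n = 3 each, log2 change 1.44, SE 0.18, adjusted p = 0.00357), and was the single gene of 7 named calls to pass in all 24 alternatives. AT1G66100 decreased 1.97-fold, from 18670 ± 576 to 9464 ± 523 (log2 change -0.98, adjusted p = 0.00357), and lost its call with no intensity trend (adjusted p = 0.0936, over a range of 3.34e-05 to 0.0936). AT2G44240 averaged 259 ± 82.7 in untreated lht1 and 3264 ± 586 after Pst (12.9-fold), and did not pass without lht1 untreated replicate 2 (3.51) or lht1 Pst replicate 2 (3.55), against 3.69 on the log2 scale, or with no intensity trend (adjusted p = 0.105, over a range of 2.38e-05 to 0.105). CHI went from 11210 ± 2235 to 22250 ± 2204 (2.01-fold), and did not pass without lht1 Pst replicate 1 (0.93) or 2 (1.02), against 1.01. It was also lost with equal medians (0.94, adjusted p = 0.0644) and with no intensity trend (adjusted p = 0.15, over a range of 0.000293 to 0.15). AT2G18690, AT5G38900 and AT1G62660 stood at 1.47, 1.39 and -0.86. AT2G18690 and AT5G38900 lost their calls without any of lht1 untreated replicates 1 and 2 and lht1 Pst replicates 1, 2 and 3 (1.29 to 1.52 and up to 1.47), and AT1G62660 lost its call without lht1 untreated replicate 1 (-0.85) or 2 (-0.83) or lht1 Pst replicate 1 (-0.75). With no intensity trend these 3 calls were lost at adjusted p = 0.0974, 0.105 and 0.105, and AT5G38900 also with equal medians (1.32, adjusted p = 0.0674) and with no filter on dim probe sets (adjusted p = 0.0701). Their adjusted p ran from 4.74e-05 to 0.0974, 0.000406 to 0.196 and 0.000277 to 0.111 over the alternatives.

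The salicylic acid response list shifted upward in lht1 after Pst (median log2 change 1.32, camera adjusted p = 0.000952), with UGT76B1 at 1.52, WRKY53 at 1.32 and GRX480 at 0.31, none of which passed over all probe sets, while 2 passed when adjusted over the list alone. The list's call was lost at adjusted p = 0.0929 with an estimated correlation (5.13e-06 to 0.0929 over the alternatives). Without lht1 untreated replicate 3 WRKY53 passed (1.94). The median was 1.89 within bot07 but -0.07 within the bot08 pair, and the adjusted p was 0.00129 with the series as a block. The photosynthesis list shifted downward (median -0.18, adjusted p = 0.000952), with SBPASE at -0.51 and PRK at -0.46, no member called and 2 passing when adjusted over the list alone. That call was lost at adjusted p = 0.123 with an estimated correlation, and also after quantile normalization (median -0.05, adjusted p = 0.396) and with fry (0.000427 to 0.396 over the alternatives). The photosynthesis medians were -0.19 within bot07 and -0.28 within the bot08 pair, with 0.000431 as the adjusted p with the series as a block. The GAPDH ratio fell in the same comparison, from 2.170 ± 0.154 to 1.714 ± 0.357. The abscisic acid, redox and reference lists did not shift (adjusted p = 0.387, 0.601 and 0.387; 0 adjusted over the list alone in each). Among the untested lists BIK1 passed when adjusted over the 2 measured members of its list, at 0.98 on the log2 scale. PDF1.2 and AT5G52810, at 1.09 and 0.48, were each the 1 measured member of a list, so their p under 0.05 was unadjusted. No gene of the untested lists passed over all probe sets.

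In lht1 18 probe sets changed after Pst, 11 higher and 7 lower, 7 of them with a single named gene, and 11 changed by at least 2-fold. The groups did not overlap for 2299 probe sets, 15.1% against 10% by chance, and 1170 had an unadjusted p under 0.05. This count moved widely: it was 110 without lht1 untreated replicate 3, 7 and 5 without replicates 1 and 2, 10, 7 and 10 without lht1 Pst replicates 1, 2 and 3, 56 with the series as a block, 177 within bot07 and 326 with array weights. Of the bot07 calls 62.2% went the same way in the bot08 pair, against 54.39% of all tested probe sets. Of the 18 calls, 12 were shared in direction with wild type and 0 were opposite, where independent lists would share 0.0509; AT2G44240, CHI and AT2G18690 were higher, and AT1G66100 and AT1G62660 lower, in both. Across all probe sets the Pst changes of the genotypes correlated at r = 0.105 (Spearman rho 0.0911), with a covariance of 0.0266 against 0.000201 in simulated unchanged groups.

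The difference of the Pst response between lht1 and wild type passed for 6 probe sets, 2 higher and 4 lower in lht1, of which 1 had a single named gene. AT2G37870, a lipid-transfer-like protein, went from 390 ± 62.4 to 177 ± 30.9 in wild type and from 234 ± 29.1 to 448 ± 21.3 in lht1 (difference 2.08 on the log2 scale, SE 0.34, adjusted p = 0.0386). Its call was lost in 13 of 23 alternatives, 4 of which changed the processing or the model, among them quantile normalization (2.04), equal medians (1.998) and no filter on dim probe sets (2.08). The other 9 left out an array: wild-type untreated replicates 1 (1.99) and 2 (2.04), lht1 untreated replicates 1 (2.07) and 2 (2.18), wild-type Pst replicates 2 (1.94) and 3 (2.11), and lht1 Pst replicates 1 (2.08), 2 (2.12) and 3 (2.05). At an unadjusted p under 0.05 there were 857 probe sets, where 759 were expected by chance. With the series as a block 11 passed, within bot07 23, without lht1 untreated replicate 3 20, and with array weights 32.

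The responses of the defence and stress genes from the fixed lists were not shown to differ between the genotypes. Their limma adjusted p ran from 0.598 for BIK1 (1.11) to 0.990 for COR15B (-0.02), with 0.953 for UGT76B1 (-0.33). In simulated data 16% of differences of log2 size 1 were recovered. The 48 probe sets higher after Pst in wild type had a median log2 change of 1.37 there and 0.49 in lht1. For the 35 lower ones the medians were -1.34 and -0.60. Both sets were picked by their change in wild type, which favours a larger change there, so these medians do not test the difference. Of the 5 tested lists the photosynthesis list passed, with a median of -0.22 (camera, adjusted p = 0.00486, 0 adjusted over the list alone). Its call was lost at adjusted p = 0.319 with an estimated correlation, and with fry (adjusted p = 0.325), and its median was 0.03 after quantile normalization (0.000435 to 0.802 over the alternatives). It also did not pass without wild-type Pst replicate 3 (-0.12) or lht1 Pst replicate 1 (-0.15), and stood at -0.21 within bot07 and -0.40 within the bot08 pair, with an adjusted p of 0.00156 with the series as a block. The low GAPDH ratio of lht1 after Pst (1.714 ± 0.357) enters this comparison too. The salicylic acid, abscisic acid, redox and reference lists did not pass (adjusted p = 0.506, 0.829, 0.628 and 0.506, with 0 adjusted over the list alone in each). Among the untested lists BIK1 passed when adjusted over the 2 measured members of its list. AT5G52810 (-0.55) was the 1 measured member of its list, so its p under 0.05 there was unadjusted.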

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

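The tests for the causes of the lower plastid transcripts were chosen after that result was seen, and the differences of the Pst response come from the planned comparison.

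Of the 6 probe sets whose Pst response differed between the genotypes, 3 had the smaller rise on the log2 scale in lht1, where their untreated level already exceeded that of infected wild type. In signal units their rises were larger in lht1. The differences in this paragraph are on the log2 scale. The brightest of the unnamed probe sets averaged 1115 ± 237 signal units in untreated wild type and 9018 ± 1209 after Pst (SD, n = 3 each), against 31550 ± 2094 and 42150 ± 1459 in lht1, a difference of -2.608 (limma, adjusted p = 4.57e-05). Of the other 2, the one that went from 286 ± 86.4 to 2604 ± 185 in wild type and from 19880 ± 3639 to 27390 ± 2868 in lht1 and the one that went from 695 ± 112 to 6000 ± 467 and from 8912 ± 604 to 20670 ± 6378 differed by -2.763 and -1.946. Another went from 2715 ± 862 to 270 ± 14.2 in lht1 and went from 543 ± 54.2 to 428 ± 50.6 in wild type (-2.945), while the last went from 356 ± 118 to 34.7 ± 12.6 in wild type and from 540 ± 234 to 634 ± 126 in lht1 (3.665). AT2G37870 differed by 2.082 and was the only one of the 6 with a named gene.

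Among gene groups the difference of the Pst response was -0.216 for photosynthesis genes, -0.324 for 68 plastid-encoded genes (60 lower, camera adjusted p = 6.06e-09) and 0.379 for 10 autophagy genes (9 higher, adjusted p = 0.0372). With an estimated correlation the photosynthesis group had an adjusted p of 0.319, the plastid group 0.104 and the autophagy group 0.492, and the photosynthesis median was 0.029 after quantile normalization. The autophagy call also ended without wild-type untreated replicate 2 (0.278), lht1 untreated replicate 3 (0.235), wild-type Pst replicate 3 (0.263) or lht1 Pst replicate 3 (0.321). The array series gave plastid medians of -0.253 within bot07 and -0.389 within the bot08 pair, and autophagy medians of 0.163 and 0.920.

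Plastid-encoded transcripts were lower in lht1 than in wild type after Pst, with 61 of 68 lower, 21 of them called, and a median log2 change of -0.436 (camera adjusted p = 1.68e-07; adjusted p = 0.166 with an estimated correlation, over a range of 6.38e-09 to 0.166). The scaling does not account for all of it: the median shrank to -0.291 after quantile normalization and was -0.487 with equal medians. The array series was split alike between the groups, so a constant difference between the series cancels here. The median was -0.441 within bot07 and -0.514 within the bot08 pair. If carry-over of RNA without poly(A) tails differed between the samples, mitochondrial transcripts could move too. Their median was 0.141, but the quartiles ran from -0.268 to 0.453. Only 11 were measured and they were much less bright than the plastid ones, so this stayed undecided. Lower expression of photosynthesis genes in infected lht1 leaves is the biological explanation tested. The nuclear photosystem genes had a median of -0.666, but camera with an estimated correlation gave an unadjusted p = 0.0842, which left it undecided. After quantile normalization their median was -0.169. The GAPDH and actin ratios were also lowest in lht1 after Pst, at 1.714 ± 0.357 and 2.538 ± 0.019 (n = 3).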

How the results depend on the processing

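The alternatives for the counts and fixed lists were set in advance, and the cause was not tested. Alternatives for LHT1 were not run, as LHT1 was not analysed here.

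Pst in lht1 moved most. Its count of 18 was 28 after quantile normalization, 28 with the filter at the 60th percentile, 11 with equal medians (5 higher and 6 lower), 11 at 2-fold, 2 with no trend, 326 with array weights, 50 with only the arrays compared, 56 with the series as a block and 177 within bot07. With an array left out it was 5 to 110. Its lists, 2, were 1 after quantile normalization, 0 with an estimated correlation, 1 with fry, and 2 to 2 with an array left out.

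Pst in wild type, 83, was 55 with no filter, 27 with no trend and 149 with array weights, and 49 to 123 with an array left out; its lists were 0 to 0. The difference of the Pst response, 6, was 32 with array weights, 11 with the series as a block and 23 within bot07, and 4 to 20 with an array left out. Its lists, 1, were 0 after quantile normalization, 0 with an estimated correlation and 0 with fry, and 0 to 2 with an array left out. The photosynthesis median there reversed to 0.029 after quantile normalization, from -0.216.

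The genotype counts were 1378 untreated and 1577 after Pst at 2-fold, and 2098 to 3097 and 2295 to 3587 with an array left out. The lists of the untreated genotypes, 2, were 3 with fry, and those after Pst, 3, were 2 after quantile normalization, 2 with an estimated correlation and 5 with fry; with an array left out they were 2 to 2 and 3 to 3. Shared changes of untreated lht1 and Pst in wild type, 52, were 33 with no filter, 32 with only the arrays compared, and 33 to 76 with an array left out. Shared genotype changes, 1916, were 922 at 2-fold and 1540 to 2112 with an array left out.

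With the replicate number as a block the counts were 3136, 3473, 84, 36 and 7. The call of AT2G37870 for the difference of the Pst response stood at adjusted p = 0.0533 under that block, and in wild type AT2G37870 and AT5G19120 at 0.0560 and 0.0526. The labels do not say that arrays of a number share plants or a day, and 6 of 18 same-number pairs correlated over 0.1 (-0.021 to 0.145), so the numbers were not taken as pairs. The data hint at some link all the same: the median r was 0.072 for equal and -0.047 for different numbers, and 8 of 12 arrays correlated best with their own number. Pairs of number 3, which are the bot08 arrays, ran from 0.086 to 0.141. Those of number 1 ran from -0.003 to 0.145 and those of number 2 from -0.021 to 0.105. For number 3 a link cannot be told apart from the array series.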

Other observations

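Several named groups other than the fixed lists moved with genotype or with Pst. Glutamate receptor-like channels averaged higher after Pst in wild type, 6 of 6 with a median log2 change of 1.02 (camera adjusted p = 0.00958; 0.54 within bot07 and 0.69 within the bot08 pair), and autophagy genes lower, 9 of 10 with a median of -0.35 (adjusted p = 0.0429). Both calls were lost at adjusted p = 0.453 and 0.758 with an estimated correlation. Without wild-type untreated replicate 1 (0.65 and -0.38) or wild-type Pst replicate 2 (0.84 and -0.40) neither passed, nor did the autophagy genes without wild-type untreated replicate 2 (-0.25) or wild-type Pst replicate 3 (-0.17). After Pst in lht1, 58 of 68 plastid-encoded genes averaged lower with 0 called, at a median of -0.27 (adjusted p = 7.27e-14; adjusted p = 0.0284 with an estimated correlation), while the GAPDH ratio fell from 2.170 ± 0.154 to 1.714 ± 0.357.

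Between lht1 and wild type after Pst, 5 of 7 nuclear photosystem genes were called lower in lht1, at a median of -0.67 (adjusted p = 0.0249). Of these 7, 5 (PSAN, PSAE-1, LHCB4.1, LHCB4.2 and LHCB4.3) are also in the fixed photosynthesis list, so this is largely the same result. That call was lost at adjusted p = 0.489 with an estimated correlation, after quantile normalization (-0.17), and without wild-type Pst replicate 3 (-0.48) or lht1 Pst replicate 1 (-0.64). In the same comparison, of 28 UDP-glycosyltransferases 9 rose and 5 fell, of 15 expansins and xyloglucan hydrolases 1 rose and 5 fell, and of 17 serine carboxypeptidase-like genes 1 rose and 4 fell. None of these 3 families shifted with camera, and none of the 22 did in untreated leaves.

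The tests below of the untreated genotype difference and of lht1 untreated replicate 3 were chosen after the results were seen, and the test of the wild-type Pst genes before.

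The genotype difference in untreated leaves was weighed against the array series, the scaling and a single array. The scaling and a single array do not account for it: 97.27% of the calls stayed after quantile normalization, and the lowest number of calls with an array left out was 2098. Every group was split alike between the array series, so a constant difference between the series cancels from this comparison. Of the bot07 calls 87.38% went the same way in the bot08 pair, against 67.64% of all tested probe sets. That pair holds a single array of each genotype, and the test could not have shown a constant series effect. A difference between the plants other than the knockout, such as a second mutation or growth, could also give such a pattern and was not tested.

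Without lht1 untreated replicate 3 the Pst count in lht1 rose from 18 to 110. An effect of the array series was undecided, because the highest correlation of this array's deviations with another bot08 array was r = 0.2808 over 500 probe sets, too near the set bound of 0.3. RNA degradation does not account for it, as the GAPDH ratio of this array was 2.003 against 1.344 to 2.80 on the other 11. No biological explanation was tested, and the plants of this replicate may have differed in some way that the labels do not give.

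That part of the wild-type Pst response is present in untreated lht1 leaves was predicted before the test. With the untreated wild-type arrays split so that the comparisons shared none, the covariance of their log2 changes was 0.0249 to 0.0882 over 6 splits. Simulated unchanged groups gave 0.0000948 (SD 0.0047), so the prediction was met in all 6. The simulated noise was drawn separately for each probe set, and the splits reuse the same arrays. This SD therefore leaves out noise shared by probe sets, and how far the covariance exceeds such noise stayed undecided. Of the 48 probe sets higher after Pst in wild type, 45 were called higher in untreated lht1. Of the 35 lower, 7 were called lower and 10 higher.

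Group labels were also exchanged. With 6 arrays, any split other than the real one mixes the groups compared, which widens the spread and lowers the count of probe sets. Given the large genotype difference, counts near 0 in the other genotype splits were fixed in advance. They do not show how rare the real counts are. With 10 splits of 6 arrays, too few for a share under 0.05, the real split was alone in its count, 1 of 10, for the untreated genotypes (2788, highest other 0), the genotypes after Pst (3141, highest other 0), Pst in wild type (83, highest other 3) and Pst in lht1 (18, highest other 0). For lists the same 10 splits gave as many in 3 (real 2, highest other 2), 1 (real 3, highest other 1), 10 (real 0, highest other 1) and 2 (real 2, highest other 2). Of the 4 splits of untreated arrays that put both bot08 arrays in 1 group, 2 also gave 2 lists and 2 gave 0, and with the series as a block 2 lists shifted. Of 100 drawn splits, 1 gave as many probe sets for the difference of the Pst response (6, highest other 1), 34 as many lists (1, highest other 3), and 1 as many shared genotype changes (1916, highest other 2). The splits for the difference moved labels over all 12 arrays and so mixed the genotypes, which widens the spread. They cannot show how rare either count would be with no difference of response. Those for the shared genotype changes exchanged the genotypes within each treatment, which lowers the count in the same way, so they cannot show how rare 1916 is. For changes shared by untreated lht1 and Pst in wild type 3 of 100 gave as many, with 1834 the highest against 52. The 2 splits beside the real one made the 3 lht1 arrays the shared control, so their counts (1797 and 1834) follow the genotype difference, and the other 97 gave at most 2. Nearly all of these 97 mixed lht1 and wild-type arrays in a group, which widens the spread and lowers the count. They therefore cannot show how rare 52 shared calls are. A split that kept the 3 lht1 arrays together as their own group gave 1 shared call. That table of splits was made after the result was seen.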
